A study of Homo sapiens with 6 samples.

How the data were processed

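HT-29 cells were grown for 24 h with or without 5 mg/ml GMP, with 3 independent biological replicates per group per the labels, and total RNA with added spike-in transcripts was copied into Cy3-labelled cRNA and hybridised to one-colour Agilent oligonucleotide arrays, 1 per sample. The deposited scanner tables hold spot intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers and versions 10.7 and 10.7.3.1 per the submitters' processing notes. The processed signal in them is background-subtracted intensity per the file headers. The authors also deposited a table of log2 values for 35169 probes. How its probes were chosen and normalised is not given in the sources used here. Each column of that table correlated with the log2 processed signal of its own array at r of 0.9997 or more with a slope between 0.967 and 1.01, which settles scale and direction, and the median of every column was 6.89, so the columns had been set to a common centre. It was used only as an alternative. It held all 20246 probes of the main analysis.

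The main values were log2 of the processed signal minus each array's 75th percentile of it over the 58717 non-control spots. The 4259 control spots and spots marked as non-uniform or population outliers (273 to 321 per array) were left out, and spots of one probe were averaged. Of 50599 probes, 27373 were well above background on at least 3 of the 6 arrays, whatever the group, and had values on at least 4. For each gene name the brightest kept probe stood for the gene, which left 20246 genes of the 36122 names on the array. Gene names came from the files, and were updated through accessions, symbols and unambiguous synonyms to the RefSeq table of assembly GRCh38.p14. Of the tested names, 15494 matched and 4752 kept the name in the files. Where several file names led to 1 symbol, the brightest stood for it in lists. Positions are those of the array annotation in hg19, and coordinates of the reference table were not used.

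Groups were compared with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 (residual df 4, prior df 2.35). A gene with no probe well above background on any array of a group has only a bound there. Its bound is the mean of the brighter group against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. This applied to 117 genes in untreated and 76 in GMP arrays. The 31 gene lists were written before the data were examined, and the 30 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01. With an estimated correlation 0 of the 30 lists passed, so no list call holds under both. The estimated correlation was 0.499 in the cholesterol list, 0.534 in the list of ATF4 targets and 0.515 in that of DNA replication. In the antimicrobial list it was -0.0190, below the preset value, yet camera's unadjusted p went from 1.21e-07 to 0.00483. In the lists of mucin and goblet cell genes and of enterocyte genes it was -0.0204 and 0.00599, and their calls were lost too. A correlation above the preset value therefore does not account for the loss in these lists.

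Genes to name were set by a rule fixed before the data were examined. Among genes with a current symbol that is not a placeholder, past the test, with no overlap between the arrays of the groups and well above background on all arrays of a group, the 12 largest rises and the 12 largest falls were named. To these came up to 4 members with the smallest p of each list with a member past the test, up to 2 of the other lists, and always CXCL8 and MUC2. The rule gave 138 genes, and the main text names only part of them. Which list members to name was chosen after their values, and their values under the alternatives, had been seen, and favoured members that kept their calls, so the named members look steadier than the rule's full set. The sensitivity counts therefore use the full set, less 1 gene left out on request. ABCG1 and SLC30A1 fall outside the rule and were named for the tests in the closing section, ABCG1 after its value was seen.

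The pipeline was tested on simulated arrays of the same 20246 genes in which 200 were changed. At log2 changes of 0.5, 1, 2 and 3 it recovered 18%, 70%, 88% and 98% of 50 genes each, with 9 false calls. It recovered a changed list with 0 false calls among the other lists. Genes were simulated independently of each other, so the list result does not show how the list test behaves where genes are correlated. Changes near 0.5 were therefore mostly missed in this simulation. In the real arrays 3846 genes passed, which makes the adjusted threshold less strict, so the share missed there was not measured. Signal over background, with 55.4% to 58.6% of spots well above it, limited what could be tested, and arrays carry no counting depth. No arrays were alike enough to be taken for one hybridisation (smallest median difference within a group 0.11 on the log2 scale).

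Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile, median and cyclic loess normalisation, no dim filter or a filter on all 6 arrays, every probe on its own or the mean of a gene's probes, outlier spots kept, eBayes with trend and robust settings, array weights, the authors' value table, a replicate block, each array left out in turn, other thresholds and other list tests. Scaling to the spike-in probes was added after the file headers had shown a slide per group. Values with no scaling between arrays were used only for 1 test in the closing section, also added after the data were seen. Slide could not be fitted as a block because no slide held both groups. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.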

Results

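Transcript levels were measured in HT-29 cells, an established epithelial line from a human colon adenocarcinoma, to learn how the intestinal epithelium responds to bovine glycomacropeptide (GMP), the glycosylated part of kappa-casein that chymosin releases into whey. Cells were kept for 24 h with 5 mg/ml GMP or left untreated, and the 3 independent biological replicates of each group gave 6 one-colour oligonucleotide arrays. On each array, between 55.4% and 58.6% of the 58717 non-control spots were well above background, and no spot was saturated. Arrays within a group correlated across genes with r between 0.989 and 0.993, and arrays of different groups with r between 0.976 and 0.984 (genes are not independent replicates). All untreated arrays lay on slide 1 and all GMP arrays on slide 2, each slide scanned on its own, so slide and group cannot be told apart in any comparison below. Changes are log2 differences, GMP minus untreated, ± the SE of the limma fit with n = 3 per group, and the number of arrays limits their precision.

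Between GMP-exposed and untreated cells, the level of 3846 of 20246 genes tested differed (19.0%; limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 1894 were higher and 1952 lower in GMP-exposed cells. ABCA1, a cholesterol efflux transporter, rose 9.08-fold (log2 change 3.18 ± 0.10, adjusted p = 0.000303), and IL17C, an epithelial cytokine, rose 8.56-fold (SE 0.11 on the log2 scale, adjusted p = 0.000381). Of the falls of named genes that are not given as bounds, the largest was that of SLC39A10, a zinc importer, by 3.42 ± 0.09 (adjusted p = 0.000164). The probe for ABCA1 lies on chromosome 9 from 107543704 to 107543763 and that for SLC39A10 on chromosome 2 from 196601344 to 196601403 in the hg19 coordinates of the array annotation, which names the gene but not the exon. A log2 change of at least 1 was reached by 679 of the genes past the test, 443 higher and 236 lower.

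**Figure D1:**
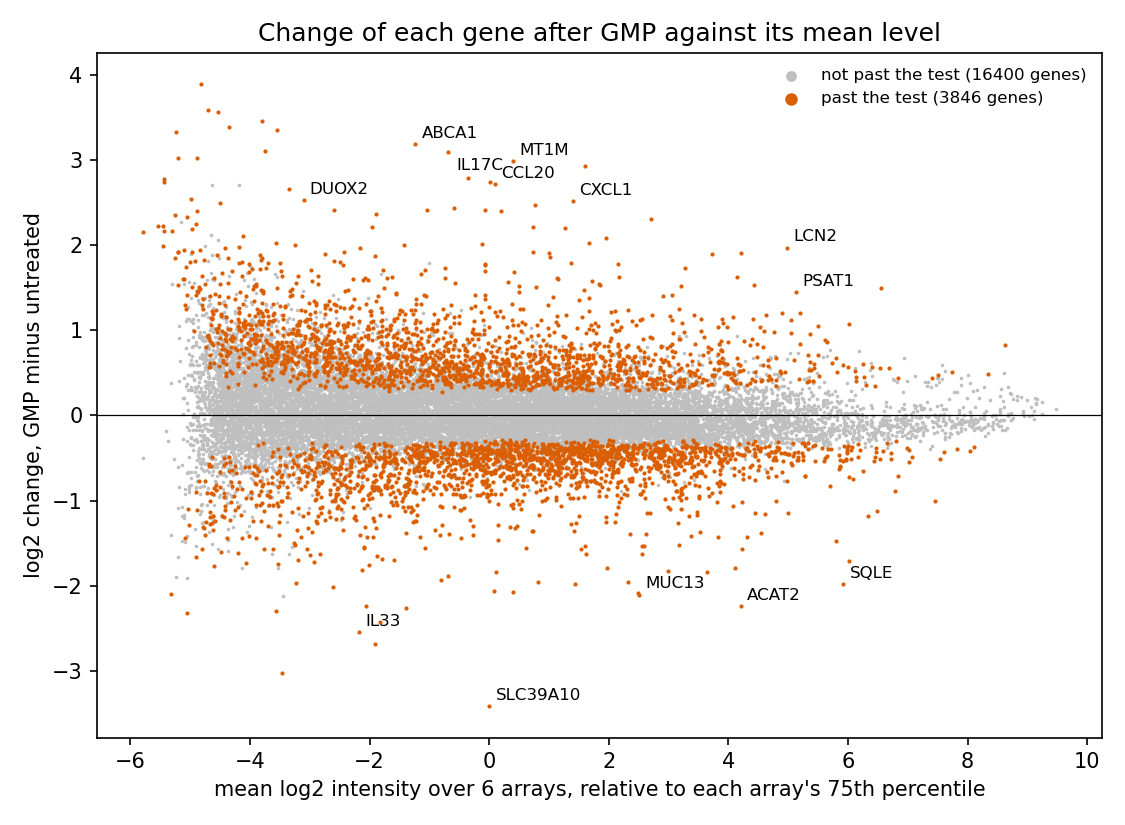
Log2 change of each of the 20246 genes (vertical axis) against its mean log2 intensity over the 6 arrays relative to the array's 75th percentile (horizontal axis). The 3846 genes past the test are in orange and lie on both sides of 0, with ABCA1 at 3.18 and SLC39A10 at -3.42 among the farthest.

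Among the other large rises, 6 genes were not well above background on any untreated array, so their changes are lower bounds. CAMP, the cathelicidin antimicrobial peptide, was at least 7.48-fold higher after GMP, and DUOXA2, the maturation factor of the oxidase DUOX2, at least 4.77-fold higher. The bounds were at least 4.48-fold for SLIT1, a secreted guidance protein, 4.01-fold for CPPED1, a phosphatase, 2.90-fold for the mucin MUC21, and 2.33-fold for GJB6, a gap junction protein. FLRT1 rose by 3.45 ± 0.57 and RTP3 8.57-fold (SE 0.27 on the log2 scale), but each was well above background on only 1 of the 3 untreated arrays, so these sizes rest on signal near background. Of the metallothioneins, MT1M rose by 2.99 ± 0.15 and MT1E by 2.93 ± 0.17.

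Among the other large falls, HEG1, an endothelial and epithelial membrane protein, was not well above background on any GMP array and was at least 7.51-fold lower. The same held for the interferon gene IFNB1, at least 1.97-fold lower, and for the kinesin KIF25, at least 1.51-fold lower. TEX19 fell by 2.68 ± 0.30, the alarmin cytokine IL33 by 2.54 ± 0.16, the serine protease FAP by 2.42 ± 0.20 and KATNAL1 by 2.30 ± 0.35, the last well above background on 1 of the 3 GMP arrays. The neurotrophin BDNF fell by 2.24 ± 0.18, ACAT2, a cytosolic acetoacetyl-CoA thiolase, by 2.24 ± 0.10, the transmembrane mucin MUC13 4.29-fold (SE 0.08) and SP5, a Wnt-responsive transcription factor, by 2.08 ± 0.17. KIF25 and IFNB1 were past the test under 10 and 14 of the 19 alternative settings that kept them.

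The count of changed genes was 1538, 1628 and 1832 without GMP replicate 1, 2 and 3 in turn, 1862 without untreated replicate 3, 1277 with no filter on dim probes and 1929 with the arrays scaled to their spike-ins. Scaling by the median moved the median change of all genes from 0.01 to -0.17 and the share of higher genes among the calls from 49.2% to 21.6% (946 higher, 3429 lower), and normexp background correction left 244 genes past 2-fold. The offset of that correction shrinks the changes of dim genes. With it the log2 change was 1.33 for FLRT1, 1.35 for RTP3 and -0.856 for KATNAL1, and each gene given above as a bound changed by less than its bound (CAMP by 1.32, HEG1 by -1.22). Falls became -1.74 for TEX19, -1.57 for IL33 and -1.46 for BDNF. Among genes named below, the change was 1.23 for DUOX2, 0.780 for SLC51A, 0.939 for SLC51B, -0.439 for GUCA2B, -1.16 for SPINK4, -0.568 for CENPI, -0.758 for CCN2, -1.12 for UGT2B7 and -0.417 for INSM1. Median scaling moved HLA-DMA to -0.524, IRAK2 to 0.354 and NFKBIA to 0.328, and the mean of a gene's probes moved SREBF1 to 0.689 and ABCC3 to 0.415. Over the main and 6 other scalings, ABCA1 ran from 2.43 to 3.23, IL17C from 2.60 to 3.14 and FAP from -2.60 to -1.67. The size of all these changes is therefore uncertain.

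Genes of sterol synthesis fell together. Of the 26 measured members of the list of cholesterol synthesis genes and SREBP2 targets, 24 fell and 0 rose, both over all genes and adjusted over the list alone, and the list's median change was -1.45. Besides ACAT2, HSD17B7, a sterol reductase, fell by 1.95 ± 0.08, SQLE, the squalene epoxidase, by 1.98 ± 0.10, and HMGCS1, the cytosolic HMG-CoA synthase, by 1.83 ± 0.10. Of the 14 lists past camera's test at its preset correlation, this one had the smallest adjusted p (6.95e-23), and the call was lost with an estimated correlation (adjusted p = 0.289). In the list of fatty acid synthesis genes and SREBP1 targets, 3 of 19 measured members rose and 6 fell (4 and 8 adjusted over the list alone), and the list was not past camera's test (adjusted p = 0.184; 0.00946, downward, by fry, which tests a list against no change, not against other genes). Its members went both ways, with SREBF1, the gene of the SREBP1 factor itself, rising by 1.08 ± 0.08 and ACLY and ACSS2, which make cytosolic acetyl-CoA, falling by 1.39 ± 0.11 and 1.43 ± 0.12.

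Genes of the amino acid response rose. Of 47 measured ATF4 targets, 34 rose and 0 fell (37 and 0 adjusted over the list alone), with a median change of 0.73 (camera adjusted p = 6.25e-15, and adjusted p = 0.471 with an estimated correlation). SLC6A9, a glycine transporter, rose by 2.09 ± 0.17, the serine synthesis enzyme PSAT1 by 1.45 ± 0.12, the proline synthesis enzyme PYCR1 by 0.96 ± 0.08 and IARS1, the isoleucyl-tRNA synthetase, by 1.09 ± 0.10. Of 40 ribosome biogenesis genes, 16 rose and 0 fell (20 and 0 adjusted over the list alone), with smaller changes. Their median was 0.31, and 0.129 with median scaling (camera adjusted p = 6.74e-05, and adjusted p = 0.471 with an estimated correlation), and LYAR and RRP12 rose by 0.66 ± 0.10 and 0.65 ± 0.10. Of 30 chaperones and genes of the unfolded protein response in the endoplasmic reticulum, 7 rose and 3 fell (14 and 4 adjusted over the list alone), and the list was not past the test (camera adjusted p = 0.438). The members that rose included HSPA5, the chaperone BiP, 2.01-fold (SE 0.11 on the log2 scale), and SEL1L, a part of the degradation machinery, by 0.97 ± 0.09.

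Antimicrobial and secretory defence genes were higher after GMP. Of 15 measured members, 8 rose and 0 fell (9 and 0 adjusted over the list alone), and the median change was 1.30, but 0.354 with no filter on dim probes, 0.523 with normexp correction and 0.754 with probes above background on all 6 arrays (camera adjusted p = 9.06e-07, and adjusted p = 0.145 with an estimated correlation). PI3, the elastase inhibitor elafin, rose by 2.73 ± 0.12, the iron-sequestering lipocalin LCN2 by 1.97 ± 0.13, and the oxidase DUOX2, well above background on 2 of the 3 untreated arrays, by 2.52 ± 0.13. Of 27 measured chemokines and cytokines, 9 rose and 5 fell (9 and 7 adjusted over the list alone), and the list as a whole was not past the test (camera adjusted p = 0.583; 0.00356 by fry, upward). Of the 10 measured CXCL genes, in the list or not, 3 rose and 3 fell, and of the 12 measured CCL genes 4 rose and 1 fell. CCL20 rose by 2.72 ± 0.11, CXCL1 by 2.52 ± 0.13 and CXCL2 by 2.01 ± 0.10, all leukocyte attractants. The labels do not say whether the GMP preparation was tested for endotoxin or whether the medium of untreated cells was changed when GMP was added, so these rises cannot be assigned to GMP itself. CXCL8, the interleukin-8 gene, did not pass the test (0.46 ± 0.19, adjusted p = 0.137).

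In the list of the NF-kB pathway and its feedback genes, 4 of 27 measured members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0581). The list passed, upward, under 6 of 20 alternative settings (adjusted p = 0.0225 with quantile normalisation, the lowest) and by fry (0.0151), and its median ran from -0.106 to 0.165 over all settings. TNFAIP2 rose by 1.20 ± 0.08, and the inhibitor NFKBIA by 0.51 ± 0.09, the latter past the test under 15 of 20 alternatives. Of 22 pattern recognition receptors and adaptors, 2 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.950), among them the adaptor MYD88, which fell by 0.61 ± 0.11, and the kinase IRAK2, which rose by 0.54 ± 0.11, past the test under 17 and 15 of 20 alternatives. Of 40 interferon response genes, 1 rose and 3 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.132). That list passed, downward, without untreated replicate 2 (median -0.37, adjusted p = 6.2e-09), with normexp correction (0.0379) and with no filter on dim probes (0.0197). IFIT2 fell by 0.93 ± 0.21 and BST2 by 0.53 ± 0.10, past the test under 14 and 13 of 20 alternatives. Of 21 antigen presentation genes, 0 rose and 1, HLA-DMA, fell by 0.34 ± 0.08, past the test under 12 of 20 alternatives, and 0 of the 21 passed adjusted over the list alone. The list's median (-0.03) changed sign among the settings (-0.217 to 0.0248), and camera's adjusted p was 0.855.

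**Figure D2:**
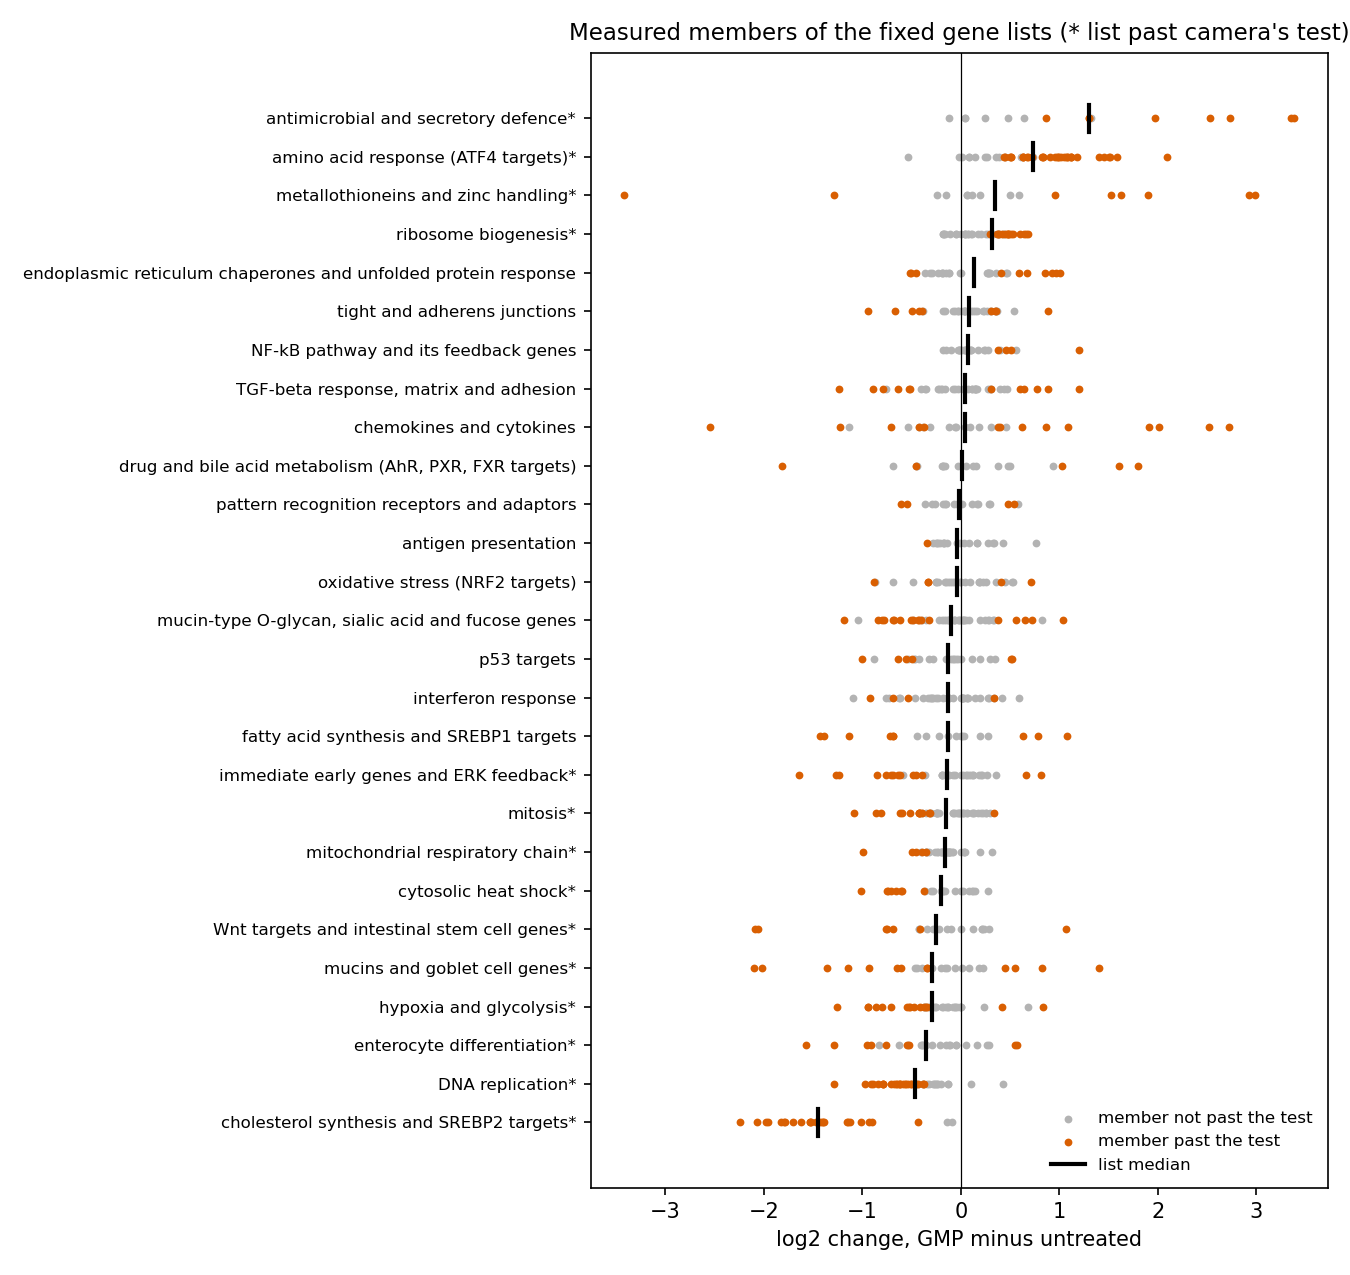
Log2 change, GMP minus untreated, of each measured member (points) of the 27 lists of pathway and epithelial genes, ordered by list median (black bars), with members past the test in orange and an asterisk on the lists past camera's test at the preset correlation. The median runs from -1.45 for cholesterol synthesis to 1.30 for antimicrobial defence, and the chemokines lie on both sides of 0.

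The list of mucin and goblet cell genes was lower on balance. Of 25 measured, 9 fell and 4 rose (10 and 4 adjusted over the list alone), with a median of -0.29 (-0.475 to -0.166 over all settings; camera adjusted p = 0.0148, adjusted p = 0.289 with an estimated correlation, and 0.0564 with median scaling). After MUC13, the falls included SPINK4 by 2.02 ± 0.28, AGR3 by 1.15 ± 0.11 and FOXA2, a goblet cell transcription factor, by 0.93 ± 0.09. MUC2, the main secreted intestinal mucin, did not pass the test (-0.14 ± 0.19, adjusted p = 0.630). Mucins as a family did not fall. Of the 11 measured genes with a MUC symbol, in the list or not, 4 rose and 1 fell. Their median was 0.00791 (-0.175 to 0.0530 over the main and 6 other scalings). Of 50 genes of mucin-type O-glycans, sialic acid and fucose, 13 fell and 5 rose (14 and 5 adjusted over the list alone; camera adjusted p = 0.146, and 0.0305 with no filter on dim probes). The fucosyltransferases FUT1 and FUT3 rose by 1.04 ± 0.10 and 0.72 ± 0.09, whereas the sialidase NEU1 fell by 0.80 ± 0.09 and CMAS, which activates sialic acid, by 0.78 ± 0.11.

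Of 27 enterocyte differentiation genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.35 (-0.536 to -0.159 over all settings; camera adjusted p = 0.00588, and adjusted p = 0.289 with an estimated correlation). The fatty acid binding protein FABP1 fell by 1.57 ± 0.17, the peptide hormone gene GUCA2B by 1.29 ± 0.12 and VIL1, the microvillus protein villin, by 0.92 ± 0.10. Of 20 Wnt targets and intestinal stem cell genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.26 (-0.438 to -0.162 over all settings; camera adjusted p = 0.0148, and adjusted p = 0.685 with an estimated correlation). DKK1, a secreted Wnt inhibitor, fell by 2.06 ± 0.11, close to SP5, and the transcription factor TCF7 fell by 0.76 ± 0.09. The member that rose was NKD2, a negative regulator of the pathway (1.07 ± 0.12), and its call was lost in the mean of its probes (0.45, adjusted p = 0.106). Of 36 genes of tight and adherens junctions, 4 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.471). CLDN2, a pore-forming claudin, fell by 0.95 ± 0.14 and CLDN1, a sealing claudin, rose by 0.88 ± 0.17, the latter past the test under 17 of 20 alternatives.

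DNA replication genes fell. Of 44 measured, 26 fell and 0 rose (35 and 0 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 3.8e-13, and adjusted p = 0.471 with an estimated correlation). CCNE2, a cyclin of S-phase entry, fell by 1.28 ± 0.14, LIG1, the replicative DNA ligase, by 0.97 ± 0.12 and RRM1, a ribonucleotide reductase subunit, by 0.91 ± 0.11. Of 44 mitosis genes, 13 fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -0.15 (-0.334 to -0.101 over all settings; camera adjusted p = 0.00775, adjusted p = 0.689 with an estimated correlation, 0.0847 without untreated replicate 1 and 0.0548 by fry). CENPI, a centromere protein, fell by 1.09 ± 0.09 and the checkpoint gene MAD2L1 by 0.81 ± 0.11.

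Of 38 hypoxia and glycolysis genes, 14 fell and 2 rose (18 and 3 adjusted over the list alone), with a median of -0.30 (-0.479 to -0.204 over all settings; camera adjusted p = 1.9e-05, and adjusted p = 0.471 with an estimated correlation). ALDOC, a glycolytic aldolase, fell by 1.26 ± 0.11 and PFKFB4, which sets fructose 2,6-bisphosphate, by 0.87 ± 0.07. Of 37 genes of the mitochondrial respiratory chain, 5 fell and 0 rose, with the same counts adjusted over the list alone, and a median of -0.17 (-0.348 to -0.0860 over all settings; camera adjusted p = 0.000331, adjusted p = 0.696 with an estimated correlation, and 0.0807 by fry). The complex I gene NDUFB6 fell by 0.99 ± 0.09. Of 23 cytosolic heat shock genes, 8 fell and 0 rose, also adjusted over the list alone, with a median of -0.20 (-0.386 to -0.158 over all settings; camera adjusted p = 0.00237, and adjusted p = 0.471 with an estimated correlation). The chaperones HSPA8, HSPE1 and HSPA1A fell by 1.01 ± 0.15, 0.75 ± 0.09 and 0.74 ± 0.09, and the probe for HSPA1A cannot be told from its near-identical copy.

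Of 38 immediate early genes and genes of ERK feedback, 12 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.14 (-0.319 to -0.0748 over all settings; camera adjusted p = 0.0130, adjusted p = 0.685 with an estimated correlation, and 0.0660 with array weights). JUN, an AP-1 subunit, fell by 1.27 ± 0.11, and CCN2, a matricellular growth factor, by 1.23 ± 0.10. CCN2 is also in the list of TGF-beta response, matrix and adhesion, in which 6 of 41 members rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.921). LAMB3, the gene of a laminin chain, rose by 1.20 ± 0.11. Of 24 p53 targets, 2 rose and 4 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.0545), with PLK2 falling by 1.01 ± 0.08. That list passed, downward, under 7 of 20 alternative settings (adjusted p = 0.0126 with no filter on dim probes, the lowest) and by fry (0.0409).

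Of 16 metallothionein and zinc handling genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.35 (0.155 to 0.393 over all settings; camera adjusted p = 0.0212, and adjusted p = 0.471 with an estimated correlation). MT1M, MT1E and MT1X (1.52 ± 0.09) rose beside the fall of SLC39A10, and because metallothionein transcripts are near-identical, the share of each paralog is uncertain. The call was lost with no filter on dim probes (adjusted p = 0.0792), with every probe tested on its own (0.0889) and on ranks (0.0605). Of 30 NRF2 targets, 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.863), with the thioredoxin gene TXN falling by 0.89 ± 0.09 and the efflux transporter ABCC3 rising by 0.71 ± 0.08. Of 20 genes of drug and bile acid metabolism, 3 rose and 2 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.921). Both subunits of the basolateral bile acid transporter rose, SLC51A by 1.79 ± 0.17 and SLC51B by 1.6 ± 0.13, and UGT2B7, a glucuronosyltransferase, fell by 1.81 ± 0.23.

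**Figure D3:**
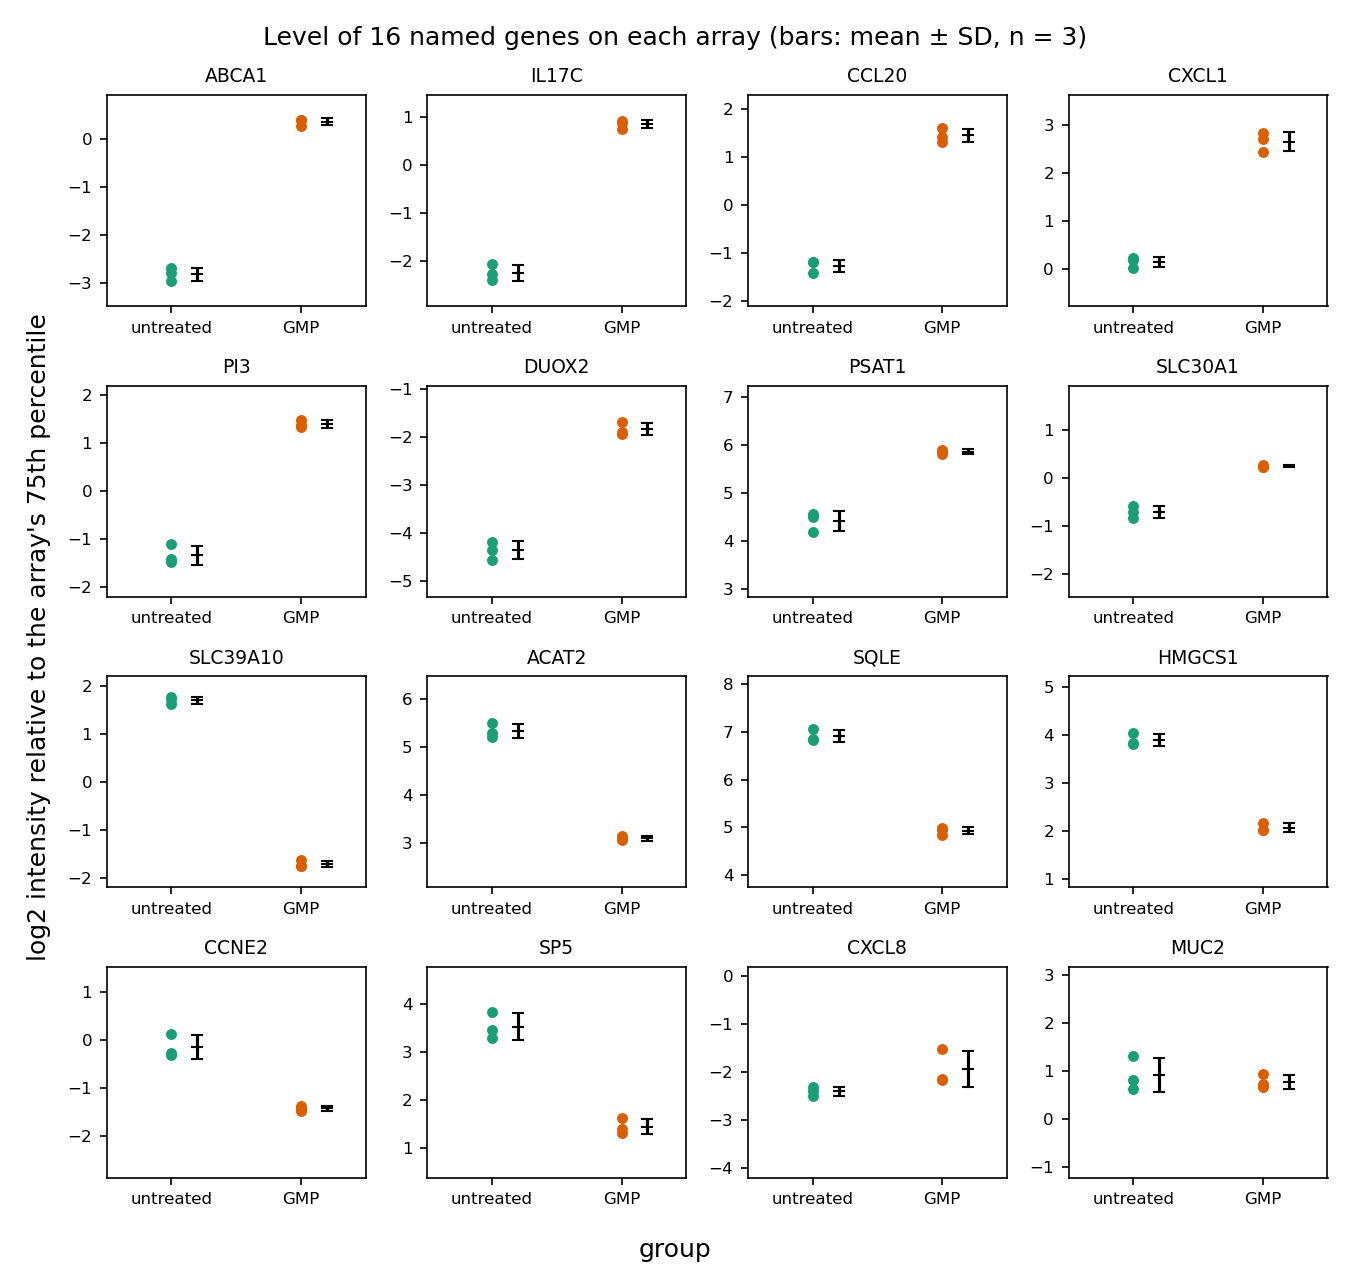
Log2 intensity relative to the array's 75th percentile of 16 genes on each of the 3 untreated and 3 GMP arrays (points), with mean ± SD of each group (bars) and the same vertical span in every panel. The arrays of the groups do not overlap for 14 of the genes or for CXCL8, whose GMP arrays are spread over an SD of 0.37, and they overlap for MUC2.

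Some markers of other cell types changed, in lists too short to compare with the 19.0% of all genes past the test. Of 6 measured fibroblast and smooth muscle markers, 0 rose and 1, FAP, fell, also adjusted over the list alone, with a median of 0.05 (-0.131 to 0.0968 over all settings) and a mean of -0.36 (camera adjusted p = 0.583; 0.0409 by fry, downward). Of 12 leukocyte markers, 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.950, with a median of -0.123 to 0.156 over all settings). Of 10 enteroendocrine markers, 0 rose and 2 fell, also adjusted over the list alone, with a median of -0.09 (-0.278 to 0.213 over all settings) and a mean of 0.03 (camera adjusted p = 0.697). INSM1, a neuroendocrine transcription factor, fell by 0.78 ± 0.16 and was past the test under 15 of 20 alternatives. Of 4 measured endothelial markers, too few for the list test, 1, ESAM, rose by 0.56 ± 0.12, past the test under 12 of 20 alternatives, and the same 1 adjusted over the list alone.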

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

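The spike-in scaling was chosen after seeing the data; the other settings were planned. Among the counts that moved by over 1.5 times, genes past the test (3846, of which 1894 higher and 1952 lower) were 1277 (655 and 622) with no filter on dim probes, where 36122 genes shared the adjustment, and 1929 (1109 and 820) with spike-in scaling, where the cause was not tested. They were 934 at an adjusted p under 0.01 and 6094 under 0.1. Leaving out 1 array gave 1538 to 2917 genes past the test, 755 to 1508 higher and 783 to 1409 lower, with fewer samples. Median scaling gave 946 higher and 3429 lower, after a shift of all genes to a median of -0.17. Genes past 2-fold fell from 679 to 244 with normexp correction, whose offset shrinks changes of dim genes. The lists past the test went from 14 to 0 with an estimated correlation in camera (4 at an unadjusted p under 0.05), against 13 on ranks, where the list of metallothioneins was lost. The test fry asks whether a list changed at all, and camera whether it changed more than other genes, so the 17 lists past fry are not calls of the same kind. They leave out mitosis and the mitochondrial respiratory chain and include chemokines, the NF-kB pathway, fatty acid synthesis, p53 targets and fibroblast markers. Lists not past the main test passed under some settings: the NF-kB pathway under 6 of 20, p53 targets under 7, interferon response under 3 and O-glycan genes under 1. Whether the replicate numbers pair the samples cannot be told from 3 per group. Correlations of deviations were 0.03, 0.14 and 0.14 for the same number and -0.205 to 0.0804 for different numbers. Not every sample correlated best with its own number. With the replicate block 2316 genes passed, 1195 higher and 1121 lower. A slide block was not run, since no slide held both groups. The 139 genes followed are all those the naming rule gave but 1, with ABCG1 and SLC30A1. Of these, 124 were past the test, 90 of them under every setting that kept the gene, and 34 lost the call under at least 1. Of the 15 not past the test, 4 changed sign under some setting. MUC2 (-0.14) ran from -0.288 to 0.0606 as 1 array was left out, and was above 0 only without untreated replicate 1. DES (0.08) was -0.105 with median scaling and ran from -0.0193 (without untreated replicate 3) to 0.189 as 1 array was left out. PLVAP (0.15) was -0.0538 with quantile normalisation, -0.0341 with median scaling and -0.0688 in the authors' table, and ran from -0.342 to 0.647 as 1 array was left out, below 0 without untreated replicate 3 or GMP replicate 2. VWF (-0.03) was 0.00708 with normexp correction and 0.0119 with spike-in scaling, and ran from -0.212 to 0.0698 as 1 array was left out, above 0 without untreated replicate 2 or 3 or GMP replicate 1. No list changed direction where it passed, and lists past the test in neither the main fit nor the alternative were not counted as changing direction.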

Other observations

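The 3 patterns weighed and their tests were chosen after a first fit had shown the genes with the largest changes. The scan of gene families, the test against random lists, the test of an effect on all transcripts alike and the separate tests of heat and oxidative stress were chosen after the values they measure had been seen, and the others before those values were seen. Gene symbols were grouped by their stem into 198 families of at least 10 measured members. With limma's camera, 13 families passed at the preset correlation and 0 with an estimated one (adjusted p = 0.971 for each, and 2 at an unadjusted p under 0.05). Probes for small nucleolar RNAs, which guide the modification of ribosomal and other RNA, gave higher signal after GMP at the preset correlation. Whether the mature RNAs or longer transcripts that contain them gave this signal was not tested. In the H/ACA class (SNORA), 23 of 90 measured members rose and 0 fell, with a median change of 0.45 (0.27 to 0.49 over the main and 6 other scalings), and in the C/D class (SNORD), 18 of 98 rose and 1 fell, with a median of 0.36 (0.17 to 0.40). Of 12 taste receptor genes (TAS), 6 rose and 0 fell, with a median of 0.88 (0.53 to 0.93). Of 12 aldo-keto reductase genes (AKR), 6 fell and 0 rose, with a median of -0.33 (-0.51 to -0.29). Of 434 zinc finger genes (ZNF), 52 rose and 18 fell, with a median of 0.14 that changed sign among the scalings (-0.04 to 0.19). No explanation of these family shifts was tested.

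The real split of the 6 arrays gave 3846 genes past the limma test, and the highest of the other 9 splits gave 0 (at an unadjusted p under 0.05, 7330 against 795). Only 1 of the 10 splits was as large, and 10 splits are too few for a share under 0.05. An effect of the slides on single probes is argued against by the next brightest probe, which went the same way in 86.3% of the 993 called genes that have one (95% exact binomial interval 84.0% to 88.4%), against 68.4% of genes not called. A slide or labelling effect on all transcripts alike as the whole cause would move all genes one way. With no scaling between arrays, 978 genes were higher and 1454 lower past the test, which argues against it. The scaling of the main values removes such a shift, so the test could add little. It does not bear on slide or labelling effects that differ between genes. Cultures, RNA preparation or labelling handled separately for each group cannot be told apart from a response to GMP, because 0 slides held both groups.

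Genes of cholesterol synthesis fell while ABCA1 and ABCG1 (2.48 ± 0.10), which export sterols, rose. An intensity-dependent bias between the slides is argued against by 10000 random lists matched on mean signal, among which the list's median of -1.45 lay at the 0.01 percentile, the smallest they can give, with -0.34 the lowest random median. Different growth of the cultures stays open and may contribute, since 2 of the 2 lists of DNA replication and mitosis also fell at the preset correlation. Sterol load acting on the LXR receptors stays undecided. Of 12 measured LXR targets other than ABCA1 and ABCG1, 4 rose and 2 fell, and the median was 0.11.

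Metallothioneins rose and the zinc importer SLC39A10 fell. Cross-hybridisation between near-identical metallothionein transcripts stays open as the reason why several of them rose. The zinc exporter SLC30A1, of unrelated sequence, rose by 0.96 ± 0.09, but this was wrongly planned as a test, since 1 metallothionein could have risen with it and lit the probes of the others. Of the cytosolic heat shock genes, 8 fell and 0 rose, with a median of -0.20 (-0.386 to -0.158 over all settings). These values argue against general heat stress still acting at 24 h, by a criterion set after they were seen. An earlier heat response that had ended by 24 h stays open, since no earlier time was sampled. General oxidative stress stays open, since 2 of the NRF2 targets rose and 3 fell and their median of -0.039 changed sign among the settings (-0.222 to 0.0459). A response to more available zinc may be a candidate explanation, as an untested hypothesis found on these data, but zinc was not measured and the handling of each group on its own slide leaves other sources open.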
